A study of Homo sapiens with 30 samples.

How the data were processed

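RNA sequencing of human diffuse large B cell lymphoma (DLBCL) cell lines was analysed in 30 libraries from 10 groups of 3 replicates. Per the labels, 24 libraries came from the lines OCI-LY3, HT, OCI-LY19 and SUDHL5, each untreated (0 h) or after 24 h in 0.2 µM doxorubicin, an anthracycline that poisons topoisomerase II. The other 6 came from OCI-LY19S, the drug-sensitive parental culture, and OCI-LY19R, its derivative with acquired resistance, which was kept in 20 nM doxorubicin until 1 week before harvest. The labels call the replicates independent experiments, though those of SUDHL5 differed so little that separate cultures are in doubt. Titles of the 24 h libraries of the 4 lines hold both the drug and the word ctrl, and these were grouped as treated from the treatment label. The labels do not say which of the 4 lines are sensitive or resistant, and no such grouping was made. No line has an untreated library at 24 h, so the drug and the time in culture change together.

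Per the labels, polyadenylated RNA was made into strand-specific libraries with a NEBNext Ultra II Directional kit and sequenced on an Illumina NextSeq instrument. Trimmomatic, STAR and featureCounts with the genome build hg38 are named in the submitters' processing notes, without versions; the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited gene-level FPKM values, which are reads divided by gene length and by the read total of the library, in one table for the 4 lines and another for OCI-LY19S and OCI-LY19R. Per the file headers, the second deposited table also holds the authors' own comparison, with a mean signal per gene, a log2 fold change, its standard error and test statistic (a score each), and raw and adjusted p-values. The tables were normalized separately, so every test stayed within a table. Each table lists 60656 genes; 60445 IDs took their symbol from the reference table of gene IDs, 49 from the deposited table, and 162 had none. GENCODE 29 on GRCh38 supplied positions, and 39344 IDs had the same version there.

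FPKM values keep the read depth when whole reads were counted. With exon-union lengths from GENCODE 29 for 25442 genes, 100.0% of values above 0 came out as whole reads within 0.01 read; the length was solved from the values for a further 19201 genes, 16010 genes were at 0 in all libraries and 3 could not be solved. Totals of the recovered reads are given in the Results. These reads served to judge depth and for 1 added alternative; the tests used the FPKM values, which the authors' length and depth scaling makes no longer counts. Genes that share sequence (HLA genes, histone genes, paralogs) and genes that overlap on opposite strands can exchange reads in such a table.

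Genes with FPKM of at least 1 in at least 3 libraries of their table were tested: 17645 in the 4 lines and 12785 in OCI-LY19S and OCI-LY19R. Values were log2(FPKM + 1), which understates the fold change of low genes. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided moderated test) fitted the 8 groups of the 4 lines together (16 residual degrees of freedom) and the resistant and parental groups alone (4 residual degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Moderated F tests asked whether the drug response differed among the 4 lines and whether the untreated lines differed, and interaction contrasts compared the responses of each of the 6 pairs of lines. Pearson and Spearman correlations of log2 changes were taken across genes, which are not independent replicates, for 10 relations.

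Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists within a comparison, and again with the correlation estimated per list. camera compares a list with the other genes tested. The 30 lists cover p53 targets, mitosis, DNA replication, histones, break repair, pro- and anti-apoptotic genes, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, mitochondrially encoded mRNAs, non-canonical and canonical NF-kB components, NF-kB targets, doxorubicin transport and metabolism, interferon-stimulated genes, MHC class I and II presentation, B cell identity, germinal center and activated B cell genes, MYC and ribosome biogenesis, ribosomal proteins, hypoxia, the unfolded protein and integrated stress responses, NRF2 targets, cholesterol synthesis, and markers of T and NK, myeloid, and stromal, epithelial or endothelial cells.

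The genes named are, per doxorubicin comparison, the 5 rising and 5 falling genes of largest change (10 and 10 for OCI-LY19R against OCI-LY19S) among those past the threshold, with no overlap between replicates and a mean FPKM of at least 10 in the higher group; clone-based, pseudogene, immunoglobulin and most non-coding symbols were left out by pattern, and genes with no symbol were left out. Added to these are the 5 genes with the largest F for differing responses and 2 per untreated line, under the same limits, up to 4 passing members of each list (or the 2 with the highest level where none passes), and 14 fixed genes. The groups, tests, lists, naming rule and alternative settings were set before the data were examined.

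The alternatives were a pseudocount of 0.1, no filter, a filter at FPKM 5, rescaling to a common sum (TPM scale), median-of-ratios scaling, quantile normalization, the replicate number as a block, the trailing tag of the library name as a covariate, the libraries of each line alone, an estimated list correlation, and each library left out in turn. 3 were chosen after seeing the data: voom on the recovered reads, the authors' deposited comparison, and every result without OCI-LY19S replicate 1. Library names in the labels fall into different series for OCI-LY3, HT and OCI-LY19 on one side and SUDHL5 on the other, so in untreated levels a batch of libraries and that line cannot be told apart. Replicate numbers were taken to pair untreated with treated libraries in HT, where all 3 same-numbered pairs deviated together (correlations 0.167, 0.32 and 0.347 across genes). The HT values reported come from the fit without this pairing, unless the replicate block is named.

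The procedure was tested on simulated data with known changes in 100 genes per size. At a log2 change of 1 it recovered 95% in OCI-LY3, 95% in HT, 91% in OCI-LY19 and 95% in SUDHL5, and 63%, 62%, 67% and 73% at 0.5. For OCI-LY19R against OCI-LY19S it recovered 59% at 1 and 20% at 0.5, so changes below 2-fold were mostly not detectable there. Unchanged genes called were 7, 12, 10, 17 and 1 in that order. In simulated HT data a shifted list passed (adjusted p = 1.48e-55) and 0 of 29 unshifted did. Correlated genes were untested. Recovery and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9.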

Results

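The data are gene expression profiles of DLBCL cell lines, grown from B cell lymphomas. In 4 lines the profiles ask what 24 h of doxorubicin changes, and in OCI-LY19S and OCI-LY19R what differs in a single resistant derivative. Its resistance cannot be told apart from its other culture history. Recovered read totals were 24042778 to 27453170 in OCI-LY3, 16067405 to 38337869 in HT, 25630629 to 35270765 in OCI-LY19 and 17849508 to 28327767 in SUDHL5. They were 18354091, 20558372 and 121769119 in OCI-LY19S and 33439107, 26419983 and 23782084 in OCI-LY19R. Levels below are mean ± SD FPKM over 3 libraries, the first group before the second. Changes are log2 ± the standard error of the limma fit on log2(FPKM + 1), with limma's adjusted p. Unless another count is given, counts of list members adjusted over the list alone equalled those over all genes tested. List tests are camera's and compare a list with the other genes. Their p, with the preset or an estimated correlation, is adjusted over the lists.

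In OCI-LY3, doxorubicin was followed by lower MYC and ribosome biogenesis genes, lower B cell identity genes, and higher NF-kB targets, NFKB2 and RELB. With an estimated correlation these lists did not pass (p = 0.0901 to 0.64). MYC, the growth-promoting transcription factor on chromosome 8 (ENSG00000136997.20, 127735434 to 127741434, plus strand, GRCh38), fell from 124 ± 8.06 to 18.1 ± 0.842 (-2.71 ± 0.18, adjusted p = 4.15e-10). CASC11, a long non-coding RNA gene beside MYC, fell from 12.8 ± 0.503 to 1.76 ± 0.0591 (-2.32 ± 0.15, adjusted p = 4.15e-10). All 19 MYC and ribosome biogenesis genes fell, by a mean of -1.71 relative to all genes (adjusted p = 2.14e-19, p = 0.0901 with an estimated correlation). Among them was RRS1, a ribosome assembly factor (-2.30 ± 0.26, adjusted p = 3.87e-07). The other falls of largest size were DDN (-2.30 ± 0.18, adjusted p = 3.46e-09) and MYBBP1A, a nucleolar protein (-2.22 ± 0.20, adjusted p = 1.63e-08). The largest rise was that of CDH24, a cadherin, from 0.622 ± 0.159 to 11.7 ± 1.05 (2.97 ± 0.10, adjusted p = 2.57e-13). IDH2, a mitochondrial isocitrate dehydrogenase, rose from 10.9 ± 2.43 to 85.8 ± 12.8 (2.88 ± 0.17, adjusted p = 1.77e-10). The other 3 largest rises were PFKFB4, a regulator of glycolytic flux (2.73 ± 0.34, adjusted p = 1.17e-06), TMEM54 (2.59 ± 0.14, adjusted p = 6.68e-11) and the aldolase gene ALDOC (2.50 ± 0.40, adjusted p = 2.5e-05).

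NFKB2, which encodes the p100 precursor of the non-canonical NF-kB subunit p52, rose in OCI-LY3 from 5.51 ± 0.964 to 21.4 ± 0.599 (1.79 ± 0.14, adjusted p = 3.67e-09). Its partner RELB rose from 7.06 ± 1.05 to 23.7 ± 1.12 (1.62 ± 0.13, adjusted p = 7.23e-09). MAP3K14, the NF-kB inducing kinase, rose from 4.26 ± 0.653 to 6.52 ± 0.295 (0.52 ± 0.13, adjusted p = 0.00208; adjusted p = 0.125 under quantile normalization). Of 14 non-canonical components 9 rose and 0 fell (adjusted p = 0.236), and of 20 canonical components 11 rose and 1 fell (adjusted p = 0.191). With no filter on low genes both lists passed, at 0.0247 and 0.00913. Among 25 NF-kB targets 16 rose and 0 fell (adjusted p = 0.0249, p = 0.64 with an estimated correlation). TRAF3, which restrains the pathway, was at 8.79 ± 0.313 and 8.61 ± 0.911 (adjusted p = 0.859, or 0.0445 as lower with median-of-ratios scaling and 0.0357 with voom). Of 20 interferon-stimulated genes 12 rose and 0 fell, STAT2 by 2.03 ± 0.10 (adjusted p = 2.67e-11). The interferon list's adjusted p was 0.0622. It passed with a pseudocount of 0.1 (0.0152), no filter (0.000209), the TPM scale (0.0216), median-of-ratios scaling (0.0169), quantile normalization (0.0308) and voom (0.00435). It also passed with the library-name tag as a covariate (0.0493), with the OCI-LY3 libraries alone (0.0464), and without treated replicate 1 (0.027) or 2 (0.0439), but not with a filter at FPKM 5 (0.0577). MHC class I genes rose in 11 of 13 (adjusted p = 0.00298, p = 0.143 with an estimated correlation). MHC class II genes fell in 7 of 12 and rose in 2 (adjusted p = 0.00749, p = 0.385 with an estimated correlation, p = 0.0965 with quantile normalization). CD74, the invariant chain, fell from 601 ± 36.1 to 348 ± 7.61 (-0.78 ± 0.07, adjusted p = 4.66e-08).

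Of 19 B cell identity genes 16 fell and 1 rose in OCI-LY3 (adjusted p = 3.13e-08, p = 0.0901 with an estimated correlation). The surface antigen gene CD22 fell from 172 ± 30.8 to 59.9 ± 10.2 (adjusted p = 4.34e-08). DNA replication genes rose in 21 of 28 and fell in 1 (adjusted p = 0.00441, p = 0.751 with an estimated correlation). Break repair genes rose in 15 of 27 and fell in 5 (16 and 5 adjusted over the list alone; adjusted p = 0.41). Mitotic genes fell in 7 of 25 and rose in 3. The mitotic list had a median of -0.16, adjusted p = 0.0283 and p = 0.938 with an estimated correlation. It had 0.63 with quantile normalization and 0.0858 with a filter at FPKM 5. Without untreated replicate 1, 2 or 3 its median was -0.033 (0.147), -0.26 (0.000303) and -0.003 (0.114). Of 29 p53 targets 16 rose and 5 fell (adjusted p = 0.551). CDKN1A, the p21 cell cycle inhibitor, rose from 0.743 ± 0.423 to 5.62 ± 2.05 (1.91 ± 0.16, adjusted p = 9.33e-09). MDM2, which degrades p53, was at 9.17 ± 0.979 and 7.87 ± 1.26 (-0.20 ± 0.10, adjusted p = 0.0891). MDM2 passed as lower with median-of-ratios scaling (-0.42, adjusted p = 0.00117), quantile normalization (-0.39, adjusted p = 0.00348), voom (-0.47, adjusted p = 0.000603), the library-name tag as a covariate (0.0161) and the replicate block (0.0082). Pro-apoptotic genes rose in 10 of 18 and fell in 1 (adjusted p = 0.089, or 0.00559 with no filter).

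Glycolysis genes in OCI-LY3 rose in 11 of 24 and fell in 3 (adjusted p = 0.932). PFKFB3 rose by 0.57 ± 0.11 (adjusted p = 0.000179), and hexokinase HK2 changed by -0.36 ± 0.10 (adjusted p = 0.00457). Lactate dehydrogenase LDHA was at 238 ± 13.6 and 224 ± 21.4 (adjusted p = 0.616, or 0.0402 as lower with median-of-ratios scaling and 0.0251 with voom). Hypoxia-induced genes rose in 10 of 14 (11 adjusted over the list alone). BNIP3L, a mitophagy receptor, went from 10.2 ± 0.319 to 40.7 ± 8.93 (1.87 ± 0.18, adjusted p = 6.96e-08). The hypoxia list had adjusted p = 0.0283, p = 0.751 with an estimated correlation, and 0.0524 and 0.0664 without untreated replicate 2 or treated replicate 3. Unfolded protein and integrated stress response genes fell in 9 of 17 and rose in 2 (adjusted p = 0.000184, p = 0.128 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 17 and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.933). Doxorubicin transport and metabolism genes rose in 6 of 16 and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.932). In all, 7128 genes rose and 2522 fell in OCI-LY3, 73.9% upward, with 1006 and 309 of them by at least 2-fold. Of all genes 57.4% had no overlap between untreated and treated libraries, against 10% by chance. The median of all genes was 0.16 higher after treatment, 0.21 on the TPM scale, 0.02 with median-of-ratios scaling and -0.001 with quantile normalization. The counts were 4950 and 4228 (53.9% upward) with median-of-ratios scaling and 4344 and 4197 (50.9% upward) with quantile normalization.

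In HT, doxorubicin was followed by higher expression of cholesterol synthesis, glycolysis and hypoxia-induced genes and lower MYC, ribosome biogenesis and B cell identity genes. With an estimated correlation these lists did not pass (p = 0.266 to 0.342), and the p53 targets did not with either. The largest rises were ALDOC from 18.5 ± 8.99 to 137 ± 63.6 (2.79 ± 0.40, adjusted p = 3.47e-05) and IDH2 from 4.18 ± 0.169 to 26.3 ± 7.55 (2.36 ± 0.17, adjusted p = 2.38e-08). They were followed by PFKFB4 (2.33 ± 0.34, adjusted p = 3.81e-05), DDIT4, an inhibitor of mTOR signalling (2.12 ± 0.23, adjusted p = 1.74e-06), and GPER1, an estrogen-binding receptor (1.92 ± 0.25, adjusted p = 1.61e-05). PRR15L fell most (-2.01 ± 0.15, adjusted p = 2.33e-08). CSK, the kinase that holds SRC kinases inactive, fell from 178 ± 13.4 to 59.4 ± 4.29 (-1.57 ± 0.10, adjusted p = 3.73e-09). The other 3 largest falls were LPP (-1.44 ± 0.13, adjusted p = 3.41e-07), the histone gene H2AX (-1.29 ± 0.40, adjusted p = 0.0187) and MYC from 43.0 ± 8.04 to 17.9 ± 5.19 (-1.24 ± 0.18, adjusted p = 3.42e-05). H2AX did not pass without untreated replicate 1 (0.0654) or 2 (0.0554) or treated replicate 3 (0.0979).

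All 17 cholesterol synthesis genes rose in HT (adjusted p = 1.87e-09, p = 0.342 with an estimated correlation). Examples were MVD, an enzyme of the mevalonate pathway (1.44 ± 0.19, adjusted p = 1.98e-05), and INSIG1 (1.23 ± 0.20, adjusted p = 0.000151). Of 24 glycolysis genes 18 rose and 0 fell (19 adjusted over the list alone; adjusted p = 1.15e-06, p = 0.342 with an estimated correlation). PFKFB3 rose by 1.02 ± 0.11 (adjusted p = 1.47e-06) and LDHA from 158 ± 36.9 to 259 ± 21.9 (0.73 ± 0.13, adjusted p = 0.000226). HK2 rose by 0.66 ± 0.10 (adjusted p = 6.37e-05) and the glucose transporter SLC2A1 by 0.47 ± 0.11 (adjusted p = 0.0027, or 0.0566 with the HT libraries alone). Hypoxia-induced genes rose in 11 of 14 (12 adjusted over the list alone; adjusted p = 3e-06, p = 0.342 with an estimated correlation). BNIP3L went from 17.9 ± 4.80 to 50.1 ± 13.5 (1.43 ± 0.18, adjusted p = 1.25e-05). MYC and ribosome biogenesis genes fell in 16 of 19 (17 adjusted over the list alone; adjusted p = 1.27e-11, p = 0.266 with an estimated correlation). B cell identity genes fell in 11 of 19 and rose in 2 (adjusted p = 1.35e-05, p = 0.266 with an estimated correlation). Mitotic genes fell in 7 of 25 (adjusted p = 9.84e-05, p = 0.703 with an estimated correlation).

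NFKB2 in HT rose from 6.07 ± 0.931 to 16.7 ± 3.16 (1.32 ± 0.14, adjusted p = 1.45e-06) and RELB from 4.28 ± 1.10 to 11.6 ± 1.32 (1.27 ± 0.13, adjusted p = 1.3e-06). BIRC3, a ubiquitin ligase of the pathway, rose from 26.8 ± 4.33 to 55.4 ± 12.2 (1.01 ± 0.18, adjusted p = 0.00031). MAP3K14 was at 7.54 ± 1.56 and 9.32 ± 2.25 (0.27 ± 0.13, adjusted p = 0.13, or 0.00877 with the replicate number as a block), and TRAF3 at 7.34 ± 1.38 and 6.95 ± 0.318 (adjusted p = 0.766). Of 14 non-canonical components 4 rose and 1 fell (adjusted p = 0.355), and of 20 canonical components 7 rose and 4 fell (adjusted p = 0.254, or 0.033 with no filter). NF-kB targets rose in 11 of 25 (12 adjusted over the list alone; adjusted p = 0.00655, p = 0.449 with an estimated correlation). MHC class I genes rose in 9 of 13 (10 adjusted over the list alone; adjusted p = 0.00124, p = 0.266 with an estimated correlation). MHC class II genes rose in 6 of 12 (adjusted p = 0.00983; 0.0692 with the HT libraries alone, p = 0.342 with an estimated correlation).

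In HT 11 of 29 p53 targets rose and 3 fell (adjusted p = 0.432). CDKN1A was at 0.151 ± 0.0246 and 0.205 ± 0.0313 (adjusted p = 0.835) and MDM2 at 6.26 ± 0.271 and 5.71 ± 0.235 (adjusted p = 0.422). Pro-apoptotic genes rose in 10 of 18 and fell in 1 (adjusted p = 0.12), and break repair genes rose in 11 of 27 and fell in 2 (adjusted p = 0.151). With no filter these lists had 0.0144 and 0.0212, and the repair list 0.0217 with quantile normalization and 0.0248 with the HT libraries alone. Stress response genes rose in 5 of 17 and fell in 6 (adjusted p = 0.327), and doxorubicin transport genes rose in 3 of 16 and fell in 1 (adjusted p = 0.541). DNA replication genes rose in 11 of 28 and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0484, p = 0.703 with an estimated correlation). The replication list had 0.0949 with median-of-ratios scaling, 0.0618 with a pseudocount of 0.1, 0.0516 with a filter at FPKM 5 and 0.0753 with voom. Without untreated replicate 2 or 3, or treated replicate 1, 2 or 3, it had 0.0897, 0.0665, 0.0523, 0.0861 and 0.0715. Interferon-stimulated genes rose in 11 of 20 and fell in 2 (adjusted p = 0.0484, p = 0.554 with an estimated correlation). That list had 0.0762 with the replicate block, 0.13 with a filter at FPKM 5, and 0.0592, 0.0679, 0.0588, 0.0599 and 0.061 without the same 5 libraries. In all, 4038 genes rose and 1661 fell in HT (70.9% upward, 185 and 52 by at least 2-fold). Of all genes 42.2% had no overlap (10% by chance). With median-of-ratios scaling 2998 rose and 2212 fell (57.5% upward), with quantile normalization 2470 and 2260 (52.2% upward).

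In OCI-LY19, p53 targets rose after doxorubicin, and genes of DNA replication, mitosis, ribosome biogenesis, break repair and glycolysis fell. With an estimated correlation the p53 list passed (p = 0.00175) and the others did not (p = 0.221 to 0.394). CDKN1A (ENSG00000124762.14, chromosome 6, 36676460 to 36687339, plus strand) rose from 23.8 ± 2.99 to 524 ± 29.3 (4.41 ± 0.16, adjusted p = 3.76e-14). MDM2 (ENSG00000135679.25, chromosome 12, 68808176 to 68850686, plus strand) rose from 12.5 ± 1.76 to 182 ± 16.9 (3.77 ± 0.10, adjusted p = 3.27e-16). The oxidoreductase gene TP53I3 rose from 6.21 ± 0.750 to 175 ± 49.4 (4.57 ± 0.14, adjusted p = 1.98e-15). All 29 p53 targets measured rose, by a median of 2.51 (adjusted p = 1.68e-19, p = 0.00175 with an estimated correlation). CSPG4, a cell surface proteoglycan, rose from 1.33 ± 0.474 to 65.1 ± 1.60 (4.85 ± 0.09, adjusted p = 7.88e-18). Also among the largest rises were METTL7A (4.28 ± 0.12, adjusted p = 1.08e-15) and CHRNA6, an acetylcholine receptor subunit (4.24 ± 0.10, adjusted p = 7.96e-17). The Ras-related GTPase gene RASD1 fell most (-3.71 ± 0.21, adjusted p = 2.15e-11). IGLL1, a surrogate light chain, fell from 508 ± 129 to 55.4 ± 43.5 (-3.41 ± 0.47, adjusted p = 3.53e-06). The other 3 largest falls were TCL1A, an AKT coactivator (-2.54 ± 0.20, adjusted p = 2.71e-09), ALKAL2 (-2.42 ± 0.17, adjusted p = 3.36e-10) and CDC20, the activator of mitotic exit (-2.31 ± 0.22, adjusted p = 3.7e-08).

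Mitotic genes fell in 24 of 25 in OCI-LY19 (median -1.36, adjusted p = 3.78e-12, p = 0.271 with an estimated correlation). Replication genes fell in 25 of 28 (median -1.01, adjusted p = 5.49e-13, p = 0.221 with an estimated correlation). MYC and ribosome biogenesis genes fell in 19 of 19 (adjusted p = 2.98e-08, p = 0.271 with an estimated correlation). Break repair and checkpoint genes fell in 22 of 27 and rose in 4 (adjusted p = 8.24e-06, p = 0.305 with an estimated correlation). TOP2A, the drug's target enzyme, fell from 110 ± 15.8 to 54.3 ± 15.9 (-1.04 ± 0.17, adjusted p = 2.68e-05). Pro-apoptotic genes rose in 14 of 18 and fell in 1 (adjusted p = 0.000376, p = 0.123 with an estimated correlation). BBC3, which encodes PUMA, rose by 3.22 ± 0.11 (adjusted p = 1.24e-14). Glycolysis genes fell in 15 of 24 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.000174, p = 0.394 with an estimated correlation). LDHA fell from 200 ± 4.58 to 50.2 ± 9.01 (-1.99 ± 0.13, adjusted p = 1.19e-10). HK2 changed by -0.74 ± 0.10 (adjusted p = 3.01e-06) and SLC2A1 by -0.73 ± 0.11 (adjusted p = 1.25e-05). Hypoxia-induced genes rose in 8 of 14 and fell in 1. The adjusted p of the hypoxia list was 0.048 (p = 0.596 with an estimated correlation). It was 0.0554 on the TPM scale, 0.0843 with a pseudocount of 0.1, 0.0768 with no filter, 0.0547 with the library-name tag as a covariate, 0.0683 with the replicate block, and 0.0759 and 0.0511 without untreated replicate 1 or treated replicate 3.

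NF-kB targets rose in 18 of 25 in OCI-LY19 (adjusted p = 2.9e-05, p = 0.221 with an estimated correlation). The chemokine receptor gene CCR7 rose from 17.4 ± 2.18 to 167 ± 24.4 (3.19 ± 0.13, adjusted p = 1.61e-13). NFKB2 rose from 3.12 ± 0.705 to 10.2 ± 1.56 (1.45 ± 0.14, adjusted p = 3.7e-08) and RELB from 2.79 ± 0.484 to 9.67 ± 1.37 (1.49 ± 0.13, adjusted p = 1.46e-08). TRAF3 was at 6.74 ± 0.280 and 6.46 ± 0.929 (adjusted p = 0.667). Of 14 non-canonical components 8 rose and 2 fell (adjusted p = 0.217). Of 20 canonical components 9 rose and 2 fell (adjusted p = 0.0975). The canonical list had 0.0419 with no filter and 0.0212 with quantile normalization. MHC class I genes rose in 9 of 13 and fell in 1 (adjusted p = 0.00707, p = 0.221 with an estimated correlation), and class II genes rose in 10 of 12 (adjusted p = 0.0133, p = 0.305 with an estimated correlation). Stress response genes fell in 12 of 17 and rose in 3 (adjusted p = 0.00808, p = 0.271 with an estimated correlation, 0.0844 with quantile normalization, 0.0514 with a filter at FPKM 5). Of 19 B cell identity genes 8 rose and 8 fell (9 and 8 adjusted over the list alone; adjusted p = 0.466). CD79A, a chain of the B cell receptor, fell from 160 ± 9.61 to 39.6 ± 6.41 (adjusted p = 1.33e-12). Transport genes rose in 7 of 16 and fell in 6 (adjusted p = 0.996). Cholesterol synthesis genes rose in 2 of 17 and fell in 5 (adjusted p = 0.422). Interferon-stimulated genes rose in 10 of 20 and fell in 1 (adjusted p = 0.0671, or 0.00649 with no filter, 0.0499 without untreated replicate 2 and 0.0477 without treated replicate 1).

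Some myeloid markers rose in OCI-LY19 too: ITGAM went from 0.0687 ± 0.0488 to 10.4 ± 5.75 (3.29 ± 0.21, adjusted p = 1.41e-10). All 3 myeloid markers tested rose (adjusted p = 0.0267, p = 0.221 with an estimated correlation), and 8 of 12 stayed below FPKM 1 throughout. The myeloid list did not pass with a pseudocount of 0.1 (0.0794), no filter (0.771), a filter at FPKM 5 (0.0509), the OCI-LY19 libraries alone (0.107) or voom (0.0602). Of 7 T and NK cell markers 1 rose and 1 fell (adjusted p = 0.681). MAP3K14 in OCI-LY19 went from 3.42 ± 0.0557 to 4.58 ± 0.371 (0.34 ± 0.13, adjusted p = 0.0328). The call was lost without any single library other than treated replicate 1, at most to 0.115 without treated replicate 3, and with median-of-ratios scaling (0.0535), quantile normalization (0.479), no filter (0.0532) or the library-name tag as a covariate (0.0513). In all, 6093 genes rose and 4184 fell (59.3% upward, 1337 and 536 by at least 2-fold). Of all genes 61.2% had no overlap (10% by chance). The median of all genes was 0.08 higher, 0.12 higher on the TPM scale, and -0.04 with quantile normalization, which gave 4426 and 5482 (44.7% upward).

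In SUDHL5, p53 targets, MHC genes and B cell identity genes rose after doxorubicin, and glycolysis, hypoxia-induced, cholesterol synthesis and mitotic genes fell. With an estimated correlation the p53 and both MHC lists passed (p = 0.000467 to 0.0224) and the others did not (p = 0.075 to 0.273). CDKN1A rose from 13.2 ± 0.410 to 236 ± 7.42 (4.06 ± 0.16, adjusted p = 5.34e-13) and MDM2 from 9.33 ± 0.328 to 39.8 ± 0.221 (1.98 ± 0.10, adjusted p = 1.03e-11). The secreted stress factor GDF15 rose from 0.832 ± 0.0505 to 13.4 ± 0.468 (2.97 ± 0.14, adjusted p = 4.84e-12). Of 29 p53 targets 27 rose, with a mean of 1.48 over the list relative to all genes (adjusted p = 9.94e-25, p = 0.000467 with an estimated correlation). PFKFB4 (ENSG00000114268.12, chromosome 3, 48517684 to 48562015, minus strand) fell from 51.5 ± 1.54 to 4.34 ± 0.171 (-3.30 ± 0.34, adjusted p = 2.25e-07), as did HILPDA, a lipid droplet protein (-3.07 ± 0.18, adjusted p = 1.1e-10). The other largest falls were the sterol regulator INSIG2 (-2.58 ± 0.15, adjusted p = 1.03e-10), the desaturase SCD (-2.54 ± 0.18, adjusted p = 1.21e-09) and FUT11 (-2.52 ± 0.22, adjusted p = 3.35e-08). The other largest rises were APOBEC3H, a cytidine deaminase (3.29 ± 0.14, adjusted p = 1.75e-12), HCAR3 (3.22 ± 0.18, adjusted p = 5.08e-11) and the histone gene H4C3 (3.20 ± 0.54, adjusted p = 9.3e-05).

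Glycolysis genes fell in 21 of 24 in SUDHL5 (22 adjusted over the list alone; median -0.88, adjusted p = 6.43e-13, p = 0.0841 with an estimated correlation). SLC2A1 fell from 32.9 ± 0.372 to 6.35 ± 0.485 (-2.21 ± 0.11, adjusted p = 1.24e-11), HK2 changed by -1.38 ± 0.10 (adjusted p = 2.04e-09) and LDHA went from 442 ± 9.12 to 190 ± 2.96 (-1.21 ± 0.13, adjusted p = 2.82e-07). Hypoxia-induced genes fell in 13 of 14 (median -1.80, adjusted p = 2.98e-12, p = 0.075 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 17 (adjusted p = 3.69e-07, p = 0.25 with an estimated correlation). Mitotic genes fell in 24 of 25 (25 adjusted over the list alone; adjusted p = 1.56e-09, p = 0.273 with an estimated correlation). Replication genes fell in 17 of 28 and rose in 1 (21 and 1 adjusted over the list alone; adjusted p = 1.22e-05, p = 0.343 with an estimated correlation). Break repair genes fell in 16 of 27 and rose in 1 (18 and 1 adjusted over the list alone; adjusted p = 0.000406, p = 0.343 with an estimated correlation). MYC fell from 22.8 ± 1.08 to 13.4 ± 0.856 (-0.72 ± 0.18, adjusted p = 0.00281). Its list fell in 9 of 19 and rose in 1 (adjusted p = 0.0053, p = 0.469 with an estimated correlation). TOP2A was at 102 ± 1.96 and 77.2 ± 3.08 (adjusted p = 0.0671, or 0.0299 as lower on the TPM scale and 0.000361 with the SUDHL5 libraries alone). Stress response genes rose in 4 of 17 and fell in 6 (4 and 7 adjusted over the list alone; adjusted p = 0.327). Transport genes rose in 3 of 16 and fell in 3 (adjusted p = 0.694).

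All 12 MHC class II genes rose in SUDHL5 (median 0.89, adjusted p = 2.77e-10, p = 0.014 with an estimated correlation). Class I genes rose in 11 of 13 (11, and 1 lower, adjusted over the list alone; adjusted p = 5.98e-06, p = 0.0224 with an estimated correlation). Pro-apoptotic genes rose in 12 of 18 (13 adjusted over the list alone; adjusted p = 5.98e-06, p = 0.0224 with an estimated correlation). B cell identity genes rose in 12 of 19 (adjusted p = 0.000128, p = 0.141 with an estimated correlation). Interferon-stimulated genes rose in 13 of 20 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.000406, p = 0.141 with an estimated correlation). NF-kB targets rose in 10 of 25 and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.000859, p = 0.205 with an estimated correlation). Of 14 non-canonical components 4 rose (adjusted p = 0.136, or 0.0259 with the SUDHL5 libraries alone), MAP3K14 from 5.89 ± 0.187 to 10.5 ± 0.547 (0.74 ± 0.13, adjusted p = 0.00014). Of 20 canonical components 5 rose and 4 fell (adjusted p = 0.932). NFKB2 was at 57.4 ± 1.17 and 65.7 ± 2.56 (0.19 ± 0.14, adjusted p = 0.317, or 0.00579 with the SUDHL5 libraries alone). TRAF3 was at 10.4 ± 0.565 and 9.44 ± 0.262 (adjusted p = 0.353). RELB was at 36.8 ± 0.371 and 46.5 ± 1.78 (0.33 ± 0.13, adjusted p = 0.0592). It passed with a filter at FPKM 5 (0.0469), median-of-ratios scaling (0.0318), quantile normalization (0.0338), voom (0.00883) and the SUDHL5 libraries alone (0.000537).

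Some markers of other cell types moved in SUDHL5 too: CD3D, a T cell receptor chain, went from 0.728 ± 0.0819 to 5.40 ± 1.06 (1.88 ± 0.08, adjusted p = 8.04e-13). Of 7 T and NK cell markers 3 rose and 1 fell (adjusted p = 0.0162, p = 0.141 with an estimated correlation, 0.0628 with voom, 0.671 with a filter at FPKM 5, 0.261 with the SUDHL5 libraries alone). Of 3 myeloid markers 2 rose (adjusted p = 0.0232, p = 0.141 with an estimated correlation, 0.155 with no filter). Both stromal or endothelial markers tested, of 12 listed, rose (adjusted p = 0.00467, p = 0.0648 with an estimated correlation, 0.09 with a pseudocount of 0.1, 0.134 with no filter, 0.0838 with a filter at FPKM 5). The share of reads from mitochondrial genes went from 6.05 to 6.35% per untreated library to 9.19 to 9.87% per treated library. In all, 3283 genes rose and 3506 fell (48.4% upward, 461 and 247 by at least 2-fold). Of all genes 59.9% had no overlap (10% by chance). On the TPM scale 2602 rose and 4236 fell (38.1% upward), with median-of-ratios scaling 3688 and 3224 (53.4%), with voom 3500 and 2987 (54.0%) and with no filter 4208 and 3571 (54.1%). SUDHL5 replicates lay closer than those of the other 3 lines (mean chi-square per gene on recovered reads 1.92 to 5.2, against 7.88 to 34.44). Whether they are separate cultures stays open. If not, the SUDHL5 SDs are technical spread only, and p-values of all lines, fitted together, rest on too many replicates.

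**Figure D1:**
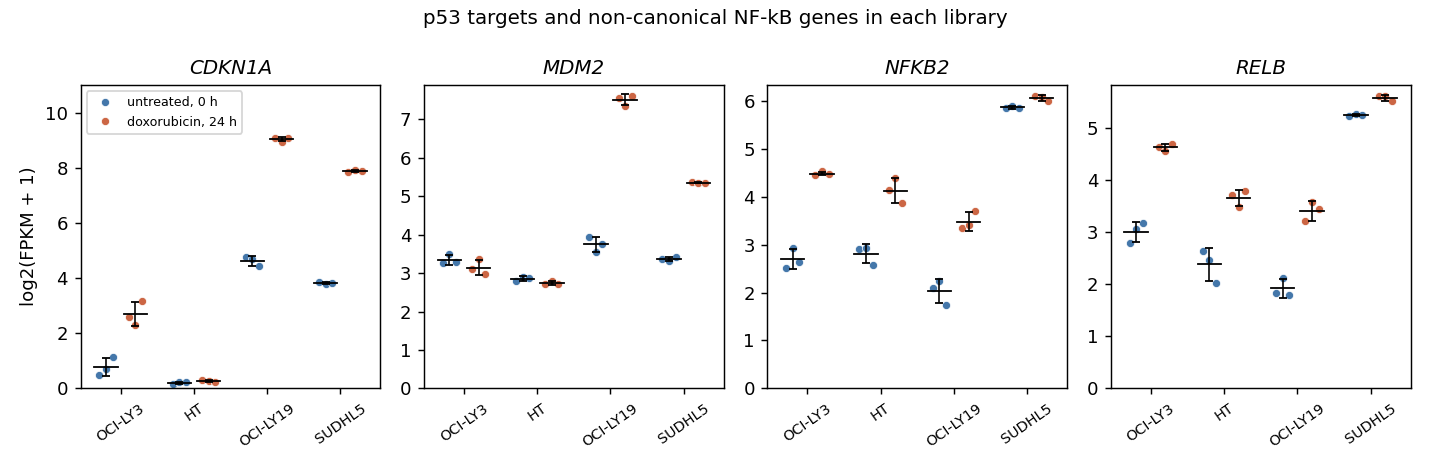
log2(FPKM + 1) of CDKN1A, MDM2, NFKB2 and RELB in each library of the 4 lines, untreated and after doxorubicin; points are libraries, the bar is the mean of 3 and the error bar its SD. CDKN1A and MDM2 rise most in OCI-LY19 and SUDHL5, while NFKB2 starts at 57.4 FPKM in SUDHL5 and at 3.12 to 6.07 FPKM in the other lines.

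The drug response differed among the 4 lines for 12737 of 17645 genes (moderated F test). Of the 5 genes with the largest F, CSPG4 changed by 0.003, -0.008, 4.85 and 0.593 in OCI-LY3, HT, OCI-LY19 and SUDHL5 (adjusted p = 4.26e-15). In the same order LDLRAD2 changed by 0.064, 0.003, 3.34 and 0.76, and HSPG2, the perlecan gene, by 0.167, 0.002, 3.98 and 0.506. PNKD changed by -0.057, 0.402, 0.713 and 2.52, and HAAO by -0.102, -0.013, 2.85 and 0.097. The p53 targets rose more in OCI-LY19 than in OCI-LY3 (difference of mean log2 changes, OCI-LY3 minus OCI-LY19, -2.17, adjusted p = 6.51e-26, p = 0.000356 with an estimated correlation). They also rose more in OCI-LY19 than in HT (-2.33, adjusted p = 6.65e-25, p = 0.000448 with an estimated correlation). SUDHL5 also exceeded OCI-LY3 (-1.18, adjusted p = 3.65e-16, p = 0.00464 with an estimated correlation) and HT (-1.34, adjusted p = 4.17e-20, p = 0.00149 with an estimated correlation). OCI-LY19 exceeded SUDHL5 (0.99, adjusted p = 2e-06, p = 0.23 with an estimated correlation), and OCI-LY3 and HT did not differ past the threshold (0.16, adjusted p = 0.833). NFKB2 rose more in OCI-LY3 than in SUDHL5 (difference 1.60, adjusted p = 1.94e-06), as it did in HT (1.13, adjusted p = 0.000169) and OCI-LY19 (1.26, adjusted p = 4.08e-05). The differences for RELB were 1.29 (adjusted p = 1.37e-05), 0.94 (adjusted p = 0.000597) and 1.16 (adjusted p = 6.18e-05). For the non-canonical list no pair of lines differed past the threshold (adjusted p = 0.501 to 0.877). SUDHL5 libraries have a name series of their own. A shift shared by all of them cancels in the drug response but not in untreated levels.

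The untreated lines differed from each other for 15976 of 17645 genes (F test). Genes high in 1 line included NSG1 in OCI-LY3 (31.1 ± 1.78), ACTL8, an actin-like cancer-testis gene, in HT (207 ± 6.64), the intermediate filament gene VIM in OCI-LY19 (220 ± 31.9) and the WNT ligand gene WNT10A in SUDHL5 (114 ± 2.39). The second gene named for each line was the transcriptional coactivator EYA2 in OCI-LY3 (28.3 ± 0.407), C11orf97 in HT (71.5 ± 4.39), the scaffold gene AKAP12 in OCI-LY19 (123 ± 6.09) and the protease inhibitor gene SPINK2 in SUDHL5 (70.7 ± 2.8). ABCB1, the drug efflux pump, was not tested in any comparison because its FPKM stayed below 1.

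**Figure D2:**
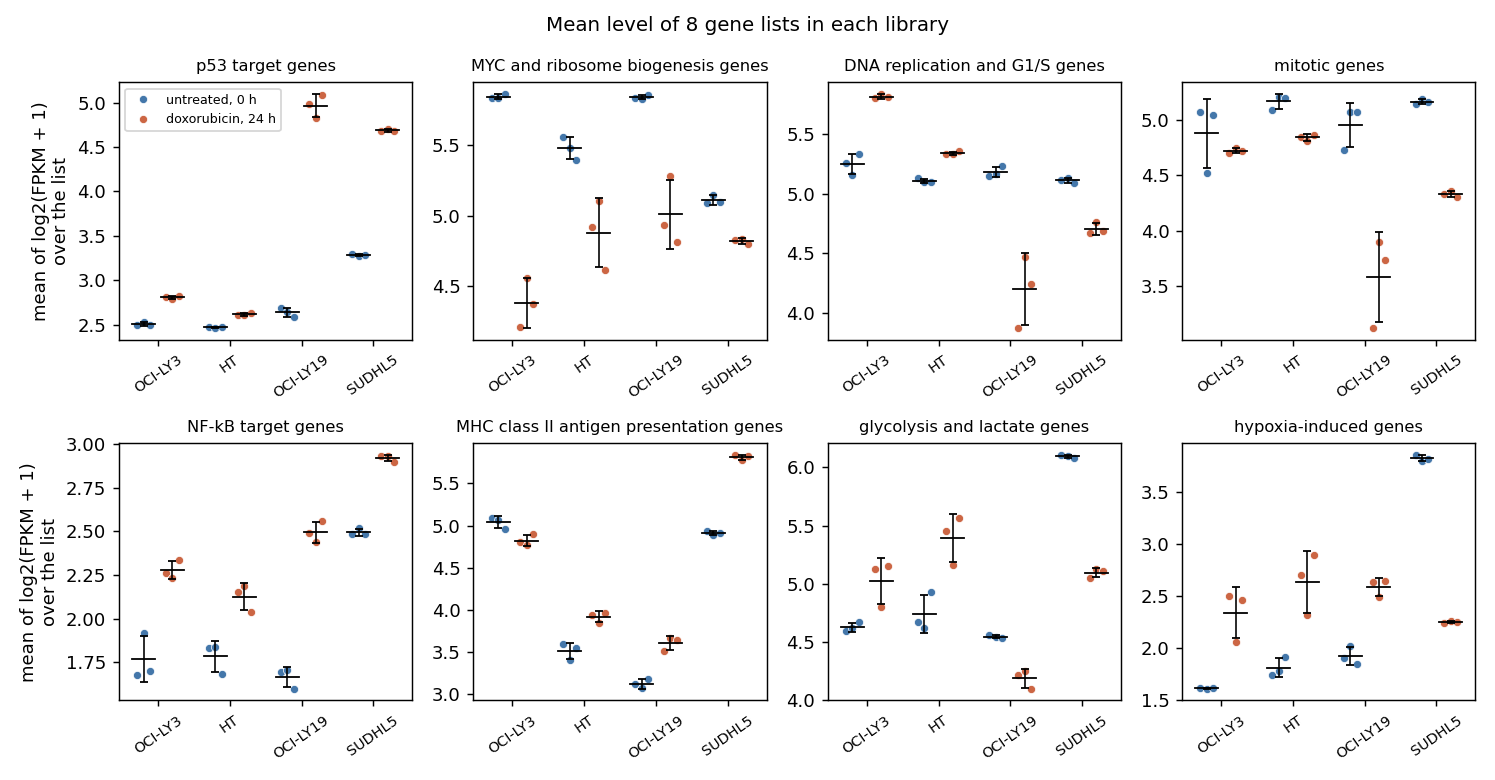
Mean log2(FPKM + 1) over the measured genes of 8 lists in each library of the 4 lines, untreated and after doxorubicin; points are libraries, bars the mean of 3 and error bars the SD. The hypoxia-induced list starts at 3.82 ± 0.03 in SUDHL5 and ends at 2.25 ± 0.006, and in HT it goes from 1.81 ± 0.09 to 2.63 ± 0.30.

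OCI-LY19R expressed more MHC class II genes and PINCR than its parent OCI-LY19S, and less CYP2W1 and VPREB3. With an estimated correlation the class II list did not pass (p = 0.608). The NF-kB and glycolysis lists did not differ past the threshold. HLA-DRA (ENSG00000204287.14, chromosome 6, 32439842 to 32445046, plus strand) was at 35.6 ± 18.0 in OCI-LY19S and 126 ± 30.3 in OCI-LY19R (1.86 ± 0.34, adjusted p = 0.0303). HLA-DQB1 was at 2.52 ± 0.544 and 9.63 ± 2.52 (1.58 ± 0.19, adjusted p = 0.01). Of 9 class II genes 8 were higher (9 adjusted over the list alone, median 1.39, adjusted p = 5.71e-08). PINCR, a p53-induced long non-coding RNA (ENSG00000224294.1, chromosome X, 43176994 to 43226598, plus strand), was at 1.26 ± 0.192 and 22.7 ± 5.33 (3.37 ± 0.18, adjusted p = 0.000815). CYP2W1, a cytochrome P450 enzyme (ENSG00000073067.14, chromosome 7, 983199 to 989640, plus strand), was at 38.9 ± 8.64 and 1.84 ± 2.43 (-4.11 ± 0.52, adjusted p = 0.0124). VPREB3, of the pre-B cell receptor, was at 13.8 ± 3.35 and 0.525 ± 0.191 (-3.27 ± 0.17, adjusted p = 0.000815). HLA-DRA did not pass without OCI-LY19S replicate 2 or any 1 OCI-LY19R library (up to 0.133 without replicate 2), nor with no filter (0.0691). CYP2W1 did not pass without OCI-LY19S replicate 2 or OCI-LY19R replicate 2 (0.0654) or 3.

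Higher in OCI-LY19R were also S100A6, a calcium-binding protein (3.13 ± 0.41, adjusted p = 0.0127), the histone gene H2BC12 (2.19 ± 0.35, adjusted p = 0.0219), the integrin gene ITGA6 (2.05 ± 0.34, adjusted p = 0.0248) and FCMR, the receptor for IgM (1.82 ± 0.32, adjusted p = 0.0286). The same held for MS4A1, which encodes CD20 (1.82 ± 0.30, adjusted p = 0.0245), EMILIN2 (1.72 ± 0.19, adjusted p = 0.00826), ALOX5AP, of leukotriene synthesis (1.67 ± 0.33, adjusted p = 0.0372), and CDC42EP3 (1.61 ± 0.20, adjusted p = 0.0124). Lower were GPER1 (-3.15 ± 0.47, adjusted p = 0.0182), ASS1, of arginine synthesis (-3.06 ± 0.42, adjusted p = 0.0148), BIK, a pro-apoptotic gene (-2.72 ± 0.48, adjusted p = 0.0283), and C12orf75 (-2.15 ± 0.18, adjusted p = 0.00404). Lower by less were PWWP2B (-2.12 ± 0.23, adjusted p = 0.00826), the lysosomal nuclease DNASE2 (-2.02 ± 0.44, adjusted p = 0.0474), the transcription factor ETS1 (-1.98 ± 0.26, adjusted p = 0.0127) and GPR146 (-1.81 ± 0.34, adjusted p = 0.0338). Of the 20 largest changes only PINCR, VPREB3 and C12orf75 passed with each library left out in turn. Without OCI-LY19R replicate 2 the others had an adjusted p from 0.0514 for PWWP2B and 0.0755 for S100A6 and ETS1 to 0.186 for DNASE2. Some also lost the call without OCI-LY19S replicate 2 or 3 or OCI-LY19R replicate 1 or 3. With no filter MS4A1 (0.0584), ITGA6 (0.0595), BIK (0.0666), GPR146 (0.0792), ALOX5AP (0.0829), DNASE2 (0.103), FCMR (0.066) and H2BC12 (0.0522) did not pass, nor did BIK with voom (0.0826).

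For the NF-kB genes, NFKB2 was at 3.59 ± 2.05 in OCI-LY19S and 3.41 ± 0.291 in OCI-LY19R (0.03 ± 0.28, adjusted p = 0.962), and RELB at 3.79 ± 2.55 and 2.79 ± 0.703 (-0.23 ± 0.34, adjusted p = 0.725). MAP3K14 was at 3.43 ± 0.547 and 3.38 ± 0.352 (adjusted p = 0.963) and TRAF3 at 8.70 ± 0.369 and 9.40 ± 0.133 (adjusted p = 0.452). BIRC3, at 0.237 ± 0.0432 and 0.126 ± 0.0328, was not tested. Of 11 non-canonical components 1 was higher (2 adjusted over the list alone; adjusted p = 0.991), the BAFF ligand gene TNFSF13B (0.98 ± 0.20, adjusted p = 0.0408). Of 18 canonical components 1 was lower (1 and 1 adjusted over the list alone; adjusted p = 0.383). Of 16 NF-kB targets 1 was higher and 1 lower (3 and 2 adjusted over the list alone; adjusted p = 0.538). The A20 inhibitor gene TNFAIP3 was at 11.7 ± 4.63 and 4.56 ± 0.474 (-1.13 ± 0.24, adjusted p = 0.0423). Among 23 glycolysis genes 1 was higher (adjusted p = 0.849), ENO2, a neuronal enolase (0.75 ± 0.14, adjusted p = 0.0322). LDHA was at 178 ± 66.0 and 198 ± 16.4 (0.23 ± 0.29, adjusted p = 0.671) and HK2 at 27.7 ± 3.55 and 28.3 ± 3.40 (adjusted p = 0.91). SLC2A1 was at 10.6 ± 1.30 and 10.7 ± 1.80 (adjusted p = 0.987) and PFKFB3 at 11.4 ± 1.64 and 9.56 ± 0.790 (adjusted p = 0.3). Leaving out 1 library ended the call of ENO2, except for OCI-LY19S replicate 1 (up to 0.119), and always that of TNFSF13B (up to 0.15). TNFAIP3 did not pass without OCI-LY19S replicate 2 or any 1 OCI-LY19R library (up to 0.174). With no filter none of the 3 passed (ENO2 0.0718, TNFSF13B 0.0906, TNFAIP3 0.0937), nor did TNFSF13B with quantile normalization (0.0586).

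MHC class I genes were higher in 2 of 13 (9 adjusted over the list alone; median 0.50, adjusted p = 5.1e-05, p = 0.608 with an estimated correlation). HLA-B was at 109 ± 22.7 and 218 ± 38.2 (adjusted p = 0.0347). B cell identity genes were lower in 3 of 14 and higher in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.000591, p = 0.608 with an estimated correlation). Break repair genes were lower in 3 of 27 (4 adjusted over the list alone; adjusted p = 9.79e-05, p = 0.608 with an estimated correlation). Among them was BLM, a helicase (-0.88 ± 0.10, adjusted p = 0.00877). Mitotic genes had a median of -0.29 (-0.47 without OCI-LY19R replicate 1) with 0 of 25 past the threshold (adjusted p = 1.04e-06, p = 0.876 with an estimated correlation). Replication genes had a median of -0.09 with 0 of 28 (adjusted p = 0.00634, p = 0.876 with an estimated correlation, 0.0556 with quantile normalization). Without OCI-LY19S replicate 1 or 3 their median was -0.20 (2.1e-06) and -0.013 (0.557). Of 24 p53 targets 3 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.911). CDKN1A was at 21.7 ± 7.21 and 42.7 ± 15.9 (0.93 ± 0.34, adjusted p = 0.165) and MDM2 at 6.47 ± 0.715 and 9.17 ± 1.46 (0.44 ± 0.13, adjusted p = 0.0977). TOP2A was at 87.5 ± 5.15 and 60.1 ± 14.1 (-0.56 ± 0.16, adjusted p = 0.0983). These 3 genes passed in the authors' deposited table (CDKN1A 0.91, adjusted p = 0.0225, MDM2 0.43, adjusted p = 0.0465, TOP2A -0.61, adjusted p = 0.0118). Transport genes were higher in 2 of 13 and lower in 1 (5 and 3 adjusted over the list alone; adjusted p = 0.768). MVP, the major vault protein, was at 0.511 ± 0.302 and 3.42 ± 1.37 (1.51 ± 0.27, adjusted p = 0.0286) and the efflux pump ABCC1 at 7.97 ± 0.626 and 12.3 ± 1.43 (0.56 ± 0.11, adjusted p = 0.0329). HLA-B, MVP and BLM lost the call without OCI-LY19R replicate 2 (0.16, 0.123 and 0.062) or 3, and HLA-B and MVP also without OCI-LY19S replicate 2. With no filter HLA-B (0.0776), MVP (0.0688) and ABCC1 (0.061) did not pass. ABCC1 lost the call without any 1 library other than OCI-LY19S replicate 1 (up to 0.132).

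Of the remaining lists in OCI-LY19R, hypoxia-induced genes were higher in 1 of 13 (3, and 1 lower, adjusted over the list alone; adjusted p = 0.538), NDRG1 by 1.38 ± 0.13 (adjusted p = 0.00509). Interferon-stimulated genes were higher in 2 of 15 and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.538), and pro-apoptotic genes lower in 1 of 16 (1 and 1 adjusted over the list alone; adjusted p = 0.772). Stress response genes had a median of -0.46 with 0 of 17 past the threshold (adjusted p = 0.0132, p = 0.608 with an estimated correlation, 0.0672 with quantile normalization, 0.101 with a filter at FPKM 5). OCI-LY19S replicate 1 stood apart on this list, with a mean log2 level of 5.36 against 4.60 and 4.70 in the other parental libraries. Without it the median was -0.12 (adjusted p = 0.00934). MYC and ribosome biogenesis genes had 0 of 19 (adjusted p = 0.775), and cholesterol synthesis genes 0 of 16 (adjusted p = 0.353, or 0.00243 as lower without OCI-LY19S replicate 1). In all, 397 genes were higher and 299 lower in OCI-LY19R (57.0% higher, 112 and 100 by at least 2-fold). Of all genes 32.7% had no overlap (10% by chance). With quantile normalization 302 were higher and 341 lower (47.0% higher). Without OCI-LY19S replicate 1, 2 or 3 the counts were 636 and 493, 50 and 56, and 176 and 215. Without OCI-LY19R replicate 1, 2 or 3 they were 253 and 146, 32 and 33, and 55 and 59. The authors' deposited table gives 1068 higher and 1110 lower genes, and 663 of the 696 called here are among them in the same direction.

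**Figure D3:**
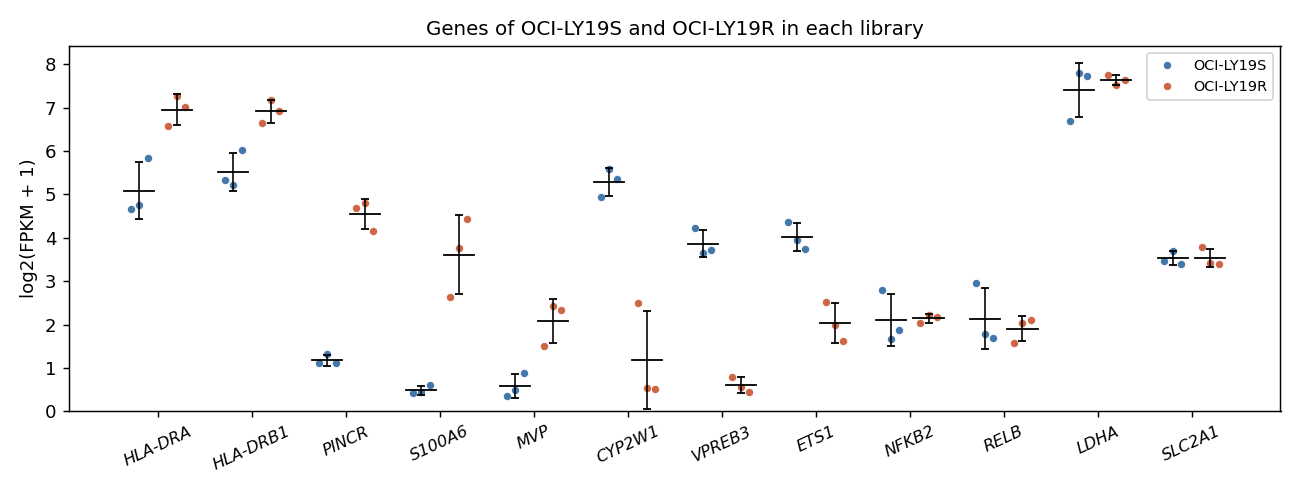
log2(FPKM + 1) of 12 genes in each OCI-LY19S and OCI-LY19R library; points are libraries, bars the mean of 3 and error bars the SD. HLA-DRA, HLA-DRB1, PINCR, S100A6 and MVP are higher in OCI-LY19R, CYP2W1, VPREB3 and ETS1 lower, and NFKB2, RELB, LDHA and SLC2A1 did not pass. Nor did HLA-DRB1 with no filter (0.0584) or without OCI-LY19S replicate 2 or OCI-LY19R replicate 2 (0.12) or 3.

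Across genes, the OCI-LY19R minus OCI-LY19S differences followed the drug response of OCI-LY19 (r = 0.26, Spearman's rho = 0.237; r = 0.374 without OCI-LY19S replicate 1) and of SUDHL5 (r = 0.168, rho = 0.192) more than that of OCI-LY3 (r = 0.041, rho = 0.068) or HT (r = 0.003, rho = -0.006). Over 12660 genes, 244 were higher in OCI-LY19R and rose with doxorubicin in OCI-LY19, against 121.6 for independent lists, and 153 were lower in both, against 92.6. Another 35 and 50 went opposite ways, against 119.9 and 93.9. Among the lines, responses correlated at r = 0.57 (rho = 0.554) for OCI-LY3 and HT, 0.427 (rho = 0.406) for OCI-LY19 and SUDHL5, and 0.306 (rho = 0.335) for OCI-LY3 and OCI-LY19. They correlated at 0.234 (rho = 0.259) for HT and OCI-LY19, 0.11 (rho = 0.12) for OCI-LY3 and SUDHL5, and 0.005 (rho = 0.035) for HT and SUDHL5. No libraries are shared between these comparisons, and genes are not independent replicates.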

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

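The tests of scaling, starting level and time in culture, the counts over other splits of the libraries, and the choice to name lists and genes called in opposite directions were made only after the results were seen. The results here were picked out because the drug response of one line differed from that of another in a test of the difference itself (limma, adjusted p). A shift shared by all SUDHL5 libraries cancels in these responses, but the starting levels of SUDHL5 cannot be told apart from a library batch. Within a line, of the lists named here only MHC class II in SUDHL5 passed with an estimated correlation (p = 0.014), and the others had p = 0.075 to 0.751.

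Responses differed among the 4 lines for 12737 genes. Of 100 draws of other splits, the labelled one included, 1 gave as many, and the highest other gave 7263. Between OCI-LY3 and HT 5194 genes differed, and 7 of 100 draws gave as many, up to 7602. The counts were 8422 for OCI-LY3 and OCI-LY19 (2 of 100 draws, highest other 11659) and 8711 for OCI-LY3 and SUDHL5 (2 of 100, 9372). They were 7976 for HT and OCI-LY19 (3 of 100, 10262) and 6531 for HT and SUDHL5 (1 of 100, 4669). For OCI-LY19 and SUDHL5 the count was 7752 (2 of 100, 10549). Every other draw as large as the labelled split kept the libraries of at least 1 line parted by treatment. Without such draws the highest other was 22 for all lines and 8, 40, 3, 10, 1 and 3 for the pairs in the order given. The other draws lose the drug response itself, so they cannot exclude a chance difference.

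Hypoxia-induced genes fell in SUDHL5 and rose in HT (difference of mean log2 changes, HT minus SUDHL5, 2.74, adjusted p = 4.79e-14, p = 0.0849 with an estimated correlation), in OCI-LY3 (2.63, adjusted p = 8.61e-09, p = 0.169) and in OCI-LY19 (2.57, adjusted p = 5.89e-10, p = 0.23). Library scaling as the whole cause is argued against, since the smallest HT minus SUDHL5 difference under 3 scalings was 2.626. A candidate explanation is a higher starting level in the untreated SUDHL5 cultures, because their lowest library lay 1.787 above the highest untreated library of the other lines in mean log2 level of the list. The list ended at 2.245 ± 0.006 in treated SUDHL5, against 2.335 ± 0.247 in OCI-LY3, 2.632 ± 0.296 in HT and 2.584 ± 0.084 in OCI-LY19. Time in culture cannot be told apart from the drug, since 0 untreated libraries were taken at 24 h, and a response of the line itself stays open and untested.

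MHC class II genes fell in OCI-LY3 and rose in HT (-0.62, OCI-LY3 minus HT, adjusted p = 1.85e-06, p = 0.171 with an estimated correlation), in OCI-LY19 (-0.70, adjusted p = 3.49e-05, p = 0.204) and in SUDHL5 (-1.12, adjusted p = 1.05e-10, p = 0.0117). DNA replication genes rose in OCI-LY3 and fell in OCI-LY19 (difference 1.55, adjusted p = 1.75e-14, p = 0.305 with an estimated correlation) and SUDHL5 (0.97, adjusted p = 1.03e-06, p = 0.393). In HT 11 of 28 rose (adjusted p = 0.0484, p = 0.703 with an estimated correlation), a call that 9 other settings ended, and HT differed from OCI-LY19 by 1.22 (adjusted p = 2.92e-14, p = 0.253 with an estimated correlation) and from SUDHL5 by 0.64 (adjusted p = 7.37e-06, p = 0.387). B cell identity genes rose in SUDHL5 and fell in OCI-LY3 (-1.02, OCI-LY3 minus SUDHL5, adjusted p = 8.94e-12, p = 0.0195 with an estimated correlation) and HT (-0.76, adjusted p = 3.86e-09, p = 0.0849). Glycolysis genes rose in HT and fell in OCI-LY19 (1.06, adjusted p = 1.48e-08, p = 0.272 with an estimated correlation) and SUDHL5 (1.73, adjusted p = 1.17e-14, p = 0.0849). Cholesterol synthesis genes rose in HT and fell in SUDHL5 (1.66, adjusted p = 5.28e-12, p = 0.164 with an estimated correlation).

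HK2 rose in HT and fell in the other lines, by a difference of -1.01 for OCI-LY3 minus HT (adjusted p = 3.27e-05), 1.39 for HT minus OCI-LY19 (adjusted p = 1.94e-07) and 2.03 for HT minus SUDHL5 (adjusted p = 2.79e-09). PFKFB3 rose in OCI-LY3 and HT and fell in OCI-LY19 and SUDHL5. Its differences were 0.96 for OCI-LY3 minus OCI-LY19 (adjusted p = 3.6e-05), 1.21 for OCI-LY3 minus SUDHL5 (adjusted p = 2.8e-06), 1.42 for HT minus OCI-LY19 (adjusted p = 4.73e-07) and 1.66 for HT minus SUDHL5 (adjusted p = 9.92e-08). LDHA rose in HT and fell in OCI-LY19 (difference 2.71, adjusted p = 6.85e-10) and SUDHL5 (1.94, adjusted p = 9.4e-08), as did SLC2A1 (1.20, adjusted p = 4.27e-06, and 2.68, adjusted p = 4.34e-10).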

How the results depend on the processing

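The voom fit, the authors' deposited table and the fits without OCI-LY19S replicate 1 were chosen only after the data were seen. Over all alternatives 308 values of gene counts stayed within 1.5 times the reported count and 29 did not. Of list tests 2280 kept their side of the threshold, 132 lost a call and 63 gained one, and for named genes these were 8451, 508 and 39. Counts of genes changed by at least 2-fold stayed within 1.5 times in 116 cases and moved further in 42, 9 of 10 with a pseudocount of 0.1. The 2-fold counts up and down with a pseudocount of 0.1 were 2829 and 507 in OCI-LY3, 831 and 112 in HT, 2540 and 811 in OCI-LY19 and 988 and 476 in SUDHL5. Voom raised all 10, to 199 and 151 in OCI-LY19R, where they ran from 30 to 134 and 30 to 119 with a library left out. Of the correlations, 147 of 148 moved by less than the spread used. No call turned its direction. For correlations a change of sign was counted only from r = 0.1 upward, a limit set after 9 of 148 values had the other sign, all with a reported r of at most 0.005.

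The number of genes that rose in OCI-LY3 was 4548 with a filter at FPKM 5 and 4344 with quantile normalization, and the number that fell was 4228 with median-of-ratios scaling, 4197 with quantile normalization and 4189 with voom. In HT 2470 rose with quantile normalization and 968 fell with its libraries alone, and in OCI-LY19 3521 rose with a filter at FPKM 5. OCI-LY19R had 247 higher and 189 lower genes with no filter, 177 and 191 with a filter at FPKM 5, and 1068 and 1110 in the authors' deposited table, and 456 were lower with voom. The count of genes that differ among the 4 untreated lines was 10242 with a filter at FPKM 5, which tests fewer genes. For the other changes the cause was not tested. With each library left out in turn, OCI-LY19R had 32 to 636 higher and 33 to 493 lower genes, and its correlation with the drug response of OCI-LY19 ran from 0.195 to 0.374. Of simulated log2 changes of 0.5, 20% were recovered in OCI-LY19R, against 62 to 73% in the 4 lines.

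Replicate numbers were taken to pair libraries in HT, where every library correlated best with its own number. There the replicate block gave 4358 rising and 1934 falling genes, ended the call of the interferon list (0.0762), made MAP3K14 pass (0.00877) and changed no other call of a list or named gene. Elsewhere not every pair's correlation of deviations was over 0.1, though same-numbered libraries of OCI-LY3 and OCI-LY19 also share a name prefix of unstated meaning, apart from untreated OCI-LY19 replicate 2. The correlations were -0.012, 0.091 and 0.362 in OCI-LY3, 0.355, 0.259 and 0.036 in OCI-LY19, -0.015, -0.014 and -0.02 in SUDHL5, and 0.012, -0.115 and 0.118 in OCI-LY19S and OCI-LY19R. The block gave 7436 and 2748 genes in OCI-LY3, 6361 and 4465 in OCI-LY19, where the hypoxia list had 0.0683, 3544 and 3831 in SUDHL5, where it ended the activated B cell list (0.0659) and made the ribosomal list (0.0299) and TOP2A (0.0182) pass, and 136 higher and 140 lower in OCI-LY19R. In OCI-LY19R it also ended 26 calls of named genes (0.052 to 0.106), among them ENO2, TNFSF13B, TNFAIP3, GPER1, ITGA6, ALOX5AP, GPR146, FCMR, ABCC1, HLA-B and HLA-DRB1, and made the myeloid (0.029) and oxidative phosphorylation (0.0457) lists pass. For the untreated lines a block numbered within each line could not be fitted. Markers of stromal, epithelial or endothelial cells gave no list test in OCI-LY19R under the reported filter.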

Other observations

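Of the tests here, the one of library scaling in OCI-LY3 and the counts over other splits were chosen only after the result was seen. Histone genes rose with doxorubicin in 12 of 17 in OCI-LY19 (median 1.82, adjusted p = 0.00151, p = 0.561 with an estimated correlation). In SUDHL5 7 of 17 rose (8 adjusted over the list alone; adjusted p = 0.00678, p = 0.528 with an estimated correlation). None passed in OCI-LY3 (adjusted p = 0.236), though H2BC12 passed as lower under 5 other settings (0.0127 to 0.048). In HT 1 fell (adjusted p = 0.0966, or 0.0105 and 0.02 without untreated replicate 3 or treated replicate 1). OCI-LY19R had 3 of 4 higher than OCI-LY19S (4 adjusted over the list alone; adjusted p = 0.00179, p = 0.608 with an estimated correlation, 0.0991 with a filter at FPKM 5). Tricarboxylic acid cycle genes fell in 14 of 16 in OCI-LY19 (adjusted p = 2.48e-06, p = 0.123 with an estimated correlation). They fell in 8 of 16 in SUDHL5 (adjusted p = 0.0127, p = 0.281 with an estimated correlation, 0.0758 with quantile normalization). In OCI-LY3 6 rose and 6 fell (adjusted p = 0.236, or 0.0477 as lower with median-of-ratios scaling), and in HT 7 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.179, or 0.0225 with no filter and 0.00725 with quantile normalization). In OCI-LY19R 1 was lower (3 adjusted over the list alone; adjusted p = 0.353, or 0.0129 without OCI-LY19S replicate 1). Nuclear oxidative phosphorylation genes fell in 18 of 29 and rose in 2 in OCI-LY19 (adjusted p = 3.93e-05, p = 0.306 with an estimated correlation). In SUDHL5 11 fell (adjusted p = 0.0053, p = 0.412 with an estimated correlation), in OCI-LY3 5 rose and 7 fell (5 and 5 adjusted over the list alone; adjusted p = 0.236, or 0.0213 as lower with median-of-ratios scaling and 0.0185 with voom), and in HT 6 rose and 1 fell (adjusted p = 0.77). None of 29 passed in OCI-LY19R (adjusted p = 0.0685, with 0.0208 with no filter, 0.0373 with a filter at FPKM 5, 0.00674 with quantile normalization, and 0.0198 and 0.00545 without OCI-LY19S replicate 2 or 3). Mitochondrially encoded mRNAs rose in 6 of 13 in SUDHL5 (adjusted p = 0.00388, p = 0.281 with an estimated correlation), but not with quantile normalization (0.814). In OCI-LY3 6 rose (adjusted p = 0.684), in HT 1 (adjusted p = 0.445) and in OCI-LY19 2 (0 adjusted over the list alone; adjusted p = 0.996). The mitochondrial list was lower in OCI-LY19R with 0 of 13 past the threshold (adjusted p = 0.0178, p = 0.876 with an estimated correlation), and it did not pass with no filter (0.188), quantile normalization (0.2), or without OCI-LY19S replicate 3 (0.114) or OCI-LY19R replicate 1 (0.289).

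Germinal center genes fell in 7 of 14 and rose in 2 in OCI-LY3 (adjusted p = 0.00116, p = 0.0901 with an estimated correlation), the repressor gene BCL6 from 78.2 ± 6.24 to 22.9 ± 0.116 (-1.72 ± 0.12, adjusted p = 8.24e-10). In HT 5 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0195, p = 0.266 with an estimated correlation, 0.135 with quantile normalization, 0.0516 with a filter at FPKM 5, 0.0599 without treated replicate 2). In OCI-LY19 4 rose and 4 fell (adjusted p = 0.876), and in SUDHL5 4 rose and 3 fell (adjusted p = 0.775). In OCI-LY19R 1 of 6 was higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.259). Activated B cell genes rose in 8 of 18 and fell in 4 in SUDHL5 (adjusted p = 0.0385, p = 0.151 with an estimated correlation, 0.0637 with quantile normalization, 0.0613 with the SUDHL5 libraries alone, 0.0519 without treated replicate 2). They rose in 7 and fell in 2 in OCI-LY3 (6 and 2 adjusted over the list alone; adjusted p = 0.932), 4 and 1 in HT (adjusted p = 0.525) and 8 and 4 in OCI-LY19 (9 and 4 adjusted over the list alone; adjusted p = 0.77), and 1 of 12 was higher in OCI-LY19R (adjusted p = 0.764). Anti-apoptotic genes rose in 6 of 11 and fell in 1 in OCI-LY3 (adjusted p = 0.73), BCL2 from 21.8 ± 3.18 to 8.78 ± 1.09 (-1.22 ± 0.09, adjusted p = 2.64e-09). In HT 4 rose and 1 fell (adjusted p = 0.964), in OCI-LY19 5 and 1 (adjusted p = 0.235), in SUDHL5 4 and 2 (5 and 2 adjusted over the list alone; adjusted p = 0.085, or 0.0422 with its libraries alone), and none of 9 passed in OCI-LY19R (adjusted p = 0.78). Ribosomal protein genes fell in 11 of 35 in OCI-LY3 (8 adjusted over the list alone; adjusted p = 2.21e-05, p = 0.685 with an estimated correlation) and 4 in HT (1 adjusted over the list alone; adjusted p = 0.00124, p = 0.703 with an estimated correlation, 0.0846 without treated replicate 2). With quantile normalization their medians were 0.034 (0.798) and 0.029 (0.808), upward. In OCI-LY19 16 rose (adjusted p = 0.0893, or 0.000138 with quantile normalization, 0.031 with a filter at FPKM 5, 0.0194 with the library-name tag as a covariate, and 0.0168 and 0.0109 without untreated or treated replicate 3). In SUDHL5 4 rose (2 adjusted over the list alone; adjusted p = 0.0503, between 0.000544 with its libraries alone and 0.0498 without untreated replicate 2 where it passed), and none of 35 passed in OCI-LY19R (adjusted p = 0.775). NRF2 targets rose in 3 of 11 and fell in 2 in OCI-LY3 (3 and 1 adjusted over the list alone; adjusted p = 0.419), rose in 3 in HT (0 adjusted over the list alone; adjusted p = 0.355, or 0.0401 with quantile normalization), and rose in 3 and fell in 6 in OCI-LY19 (adjusted p = 0.101, or 0.0195 with no filter and 0.0414 without treated replicate 1). In SUDHL5 2 fell (adjusted p = 0.568) and none of 11 passed in OCI-LY19R (adjusted p = 0.924).

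T and NK cell markers rose in 2 of 7 in OCI-LY3 (adjusted p = 0.934) and 2 in HT (adjusted p = 0.4), and 1 of 3 was higher and 1 lower in OCI-LY19R (2 and 1 adjusted over the list alone; adjusted p = 0.764). Of 3 myeloid markers 1 rose in OCI-LY3 (adjusted p = 0.933), 0 in HT (adjusted p = 0.77) and 0 in OCI-LY19R (2 adjusted over the list alone; adjusted p = 0.184, or 0.0356 with no filter and 0.0238 without OCI-LY19R replicate 1). Of 2 stromal or endothelial markers 1 fell in OCI-LY3 (adjusted p = 0.158, or 0.0308 with quantile normalization), 0 passed in HT (adjusted p = 0.996) and 1 rose in OCI-LY19 (adjusted p = 0.681). For some lists the test, which compares with all genes, pointed down while the median was above 0. These were histones (0.20), oxidative phosphorylation (0.046), NRF2 (0.088), cholesterol (0.123) and T and NK markers (0.014) in OCI-LY3, and stress response (0.084) and myeloid markers (0.023) in HT. The same held for germinal center genes (0.055), cholesterol (0.007) and mitochondrial mRNAs (0.093) in OCI-LY19, and for MYC (0.041), ribosomal (0.020), tricarboxylic acid cycle (0.020) and pro-apoptotic genes (0.014) in OCI-LY19R. The test pointed down with a mean above 0 for tricarboxylic acid cycle genes in OCI-LY3 (0.144), and for B cell identity (0.045) and transport genes (0.168) in OCI-LY19. In SUDHL5 it pointed up for germinal center genes with a median of -0.019.

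More genes rose than fell in OCI-LY3. A few genes taking most of the reads is argued against, because the share of reads in the 10 leading genes changed by -0.3 percentage points, untreated minus treated. Library scaling cannot be told apart from a true excess, since median-of-ratios scaling centres the changes (median 0.16 before and 0.018 after) and so by itself brings the rising share of calls near to even, at 53.9%.

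Stress genes stood apart in OCI-LY19S replicate 1, with DDIT3 at 69.3 FPKM against 13.5 and 14.7 in the other parental libraries, TRIB3 at 139 against 23.1 and 25.1, and HSPA5 at 36.3 against 137 and 138. A swap with an OCI-LY19R library is argued against, since over 1129 genes this library had a median position of 0.054 between the other parental libraries (0) and OCI-LY19R (1), with quartiles of -0.292 and 0.454. Cells of OCI-LY3, HT or SUDHL5 mixed in are argued against too, as genes of those lines stood at no more than 0.332% of the line's level in the median. A different culture state may be the source and was not tested.

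Each comparison of 3 against 3 libraries allows only 10 splits, too few for a share under 0.05. The labelled split gave 9650 genes in OCI-LY3 against at most 6 in another split, 5699 against 24 in HT, 10277 against 54 in OCI-LY19, 6789 against 1 in SUDHL5 and 696 against 0 for OCI-LY19R. For the untreated lines 15976 genes differed (1 of 100 draws, highest other 6842), but draws that mix lines cannot exclude chance. Within OCI-LY19S the mean chi-square per gene on recovered reads was 13.44 between replicates 2 and 3, and 53.1 and 91.54 between replicate 1 and these.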
